A study of Rattus norvegicus with 4 samples.

How the data were processed

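Poly(A)-selected mRNA of 4 rat livers was sequenced on an Illumina MiSeq after TruSeq library preparation, per the labels' protocols. Each sample was placed in its group by its source label, and the columns of the deposited table were matched to samples by their titles. The groups naive, saline, siRNC and miR-27b each hold 1 library, and no column of the table was left without a sample. The submitters' processing notes name DESeq, with no version, and the rat genome build rn5, and the header of the deposited table names an NGS RefSeq gene entity list. The aligner and the counting tool are not given in the sources used here.

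The values are named normalized in the deposited table, and they are log2 values, as shown by values of both signs within a narrow range. They behave as log2 of size-factor-scaled reads, floored at 1 normalized read, minus 1 baseline per gene near the median of the 4 libraries. In 77.3% of the 12874 genes with a value other than 0, one of the middle libraries is at exactly 0. Therefore the table gives the difference between libraries within a gene and not the level of the gene. Of 31457 rows, 18583 are at 0 in all 4 libraries. The gene lists, the rule for named genes, the comparisons and the alternatives, apart from those named as added, were chosen before the data were examined. At that stage linear normalized values with a pseudocount of 5 and random lists matched on 20 bins of the mean had been planned. As the unit differed from that plan and was log2, the log2 fold used throughout is the difference of the deposited values with no pseudocount, and random lists were matched on the level classes described next (4 classes).

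Levels were recovered as far as the values allow. The log2 worth of 1 read was taken from the most common value among genes above 0 in 1 library alone. In the naive and miR-27b libraries this value stands for 1 read, and in the saline and siRNC libraries, where a single read lies below the floor, it was read as 2 reads and 1 was subtracted. The worth was 0.0335 for the naive, -0.0554 for the saline, -0.0078 for the siRNC and 0.0647 for the miR-27b library. These are size factors of 0.977, 1.039, 1.005 and 0.956. Read numbers were assumed to come in steps of a fixed small fraction of a read, as when a read that overlaps a gene in part is counted in part. A search over up to 200 reads with a posterior above 0.9 recovered the reads of 3733 genes (29.0%). Of the recovered values of kept genes, 67.7% were whole (within 1e-06 of a read). For other genes a level class was inferred from the binary rounding of the stored values: at least 16 normalized reads, or at least 256, each with a probability of at least 0.5. Kept were 1605 genes with recovered reads and a mean of at least 10 normalized reads, 5788 in the class of at least 16, 2430 in the class of at least 256, and 1 gene with 2 or more libraries at the floor, in all 9824. For genes without recovered reads the class refers to the baseline near the median library, not to the mean, so genes high in 1 library alone are kept less often. A stricter set of 2999 genes required a mean of at least 50 or the class of at least 256 reads. Total reads per library cannot be derived from within-gene differences and were not used here.

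Log2 folds were computed for 4 main comparisons, and for the siRNC and miR-27b against the naive library. A gene was described as higher or lower at 2-fold or more. For genes with recovered reads, an exact conditional binomial (Clopper-Pearson) 95% interval of the ratio was computed from reads rounded to whole numbers. It covers counting error only, since PCR copies are not independent molecules and 1 animal stands for each group. The counting SD of a log2 ratio is 0.51 at 16 reads in each library and 0.13 at 256. Counting error alone was simulated in 100 draws with the same rate in all libraries for the 1605 genes. For each of 37 gene lists, the median log2 fold was ranked among the medians of 10000 random lists of the same size and level classes. The 33 lists with at least 5 measured genes were used. The other 4 were neutrophils, T and NK cells, B and plasma cells, and mitochondrially encoded genes, with 1, 4, 1 and 0 measured genes. A list was called where its percentile was under 2.5 or over 97.5. These percentiles describe the libraries and test no condition.

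Genes named in the text follow a fixed rule. For each main comparison these were the 6 highest and 6 lowest named genes of the stricter set, 9 fixed genes (Ppargc1a, Hmox1, Il6, Tgfb1, Hgf, Ccnd1, Mki67, Alb and Afp), and up to 4 members of each called list in its direction and up to 2 in the other. The 6 highest and 6 lowest genes at least 2-fold from naive in all 3 hepatectomised livers were added. Some genes chosen by this rule are left out of the text for length, and some are not reported here. Symbols and gene IDs are those of the deposited table. Among genes described at most length, the gene IDs were 24309 for Dbp, 78968 for Srebf1, 360243 for Top2a, 367391 for Marco, 81682 for Lum, 84604 for Hamp, 499342 for Cd274 and 83681 for Cish. The IDs of 12396 genes (96.3%) matched a reference table of the GRCr8 assembly, which was used for current symbols only. No coordinates are given, because that assembly is not the build of the deposited values.

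The alternatives tried were pseudocounts of 1 and 20, no filter on low levels, a mean of at least 50, folds centred on their median, random lists without matching, the mean of a list in place of its median, and an exact binomial test of recovered reads. After seeing the data, the pseudocount of 5, planned as the main scale, became an alternative, and the count over genes with recovered reads alone was added. With a pseudocount, a gene without recovered reads was placed at the bottom of its level class, which shrinks its fold most. The procedure was tested on simulated data for the saline against naive comparison with 12827 genes. The worth of 1 read was recovered exactly. Of 9357 simulated genes with recovered reads, 89.8% had all read numbers right and 10.2% had them too low by a common factor, and none too high. Reads were recovered for 72.9% of simulated genes against 29.0% of real ones, so the simulation is simpler than the table. The filter kept 96.8% of 10909 simulated genes with a true mean of at least 10. At least 2-fold differences were found for 0.0% of 49 genes with a true log2 change of 0.5, and for 100.0% of 45, 48 and 47 genes with true changes of 1.5, 2.0 and 3.0, and for 1.20% of 10375 unchanged genes. All changed genes were simulated at a level of at least 50 reads. Their shares therefore do not cover the lower genes that the filter also keeps. Of 300 random lists of 15 genes 4.3% were called, and of 100 lists shifted by 0.5 all were. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.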

Results

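Liver RNA from Lewis rats was profiled by sequencing of poly(A)-selected transcripts on an Illumina MiSeq, in 4 libraries with 1 library per group. The groups were a naive liver and 3 livers after partial hepatectomy, the surgical removal of part of the liver, after which the remaining tissue regrows. The hepatectomised rats had received saline, cells labelled ASCs-siRNC, or cells labelled ASCs-miR27b, all into a vein. ASCs, which the labels do not spell out, is read here as adipose-derived stem cells. They are called here the naive, saline, siRNC and miR-27b livers. The time between surgery and collection is not given in the sources used here. Of 31457 genes in the deposited table, 12874 had a value other than 0 in at least 1 library, and 9824 passed the filter on low levels. The size factors of the 4 libraries, in the order named, were 0.977, 1.039, 1.005 and 0.956, so the relative depths they stand for were close. Total reads per library were not used here, because the table gives only differences within each gene.

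With 1 library per group, no difference has a replicate check and no test between conditions was made. Genes are described by the size of their log2 fold, and fixed gene lists are described by the percentile of their median log2 fold among 10000 random lists matched on level. A list is called higher or lower where its median lay outside the central 95% of those lists. Single folds also depend on the pseudocount, for which genes without recovered reads were placed at the bottom of their level class. Of 444 folds of named genes, 132 moved with a pseudocount of 5, beyond their counting interval or, without recovered reads, by 0.13 or more. Counting error alone gives a log2 fold an SD of 0.51 at 16 reads in each library and 0.13 at 256 reads. Exact conditional binomial 95% intervals are given in the 4 main comparisons for named genes whose reads could be recovered, and cover counting error only, not differences between animals.

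The first comparison asks how the liver after partial hepatectomy and saline differed from the naive liver. Of 9824 genes, 601 were at least 2-fold higher and 374 at least 2-fold lower in the saline liver. Markers of macrophages and Kupffer cells, the resident macrophages of the liver, were higher: 15 of 18 measured genes were at least 2-fold higher and their median was 1.27, above all random lists. The scavenger receptors Marco (2.5) and Cd163 (1.96) led this list. Erythroid genes had a median of 2.35 over 12 genes, also above all random lists, with Alas2, the erythroid enzyme of haem synthesis, at 3.12 and the red cell anion exchanger Slc4a1 at 3.97 (95% interval 2.34 to 6.30; 3 reads in the naive and 50 in the saline library). Haemoglobin genes may share reads with near-identical copies, so single members of that family are uncertain. The list median lies among such copies, with Hbb at 2.33, Hba1 at 2.34, and Hbb-b1 and Hba2 at 2.36. They count as separate genes, whereas random lists draw genes independently, so the percentile overstates how many separate signals moved. This limit holds wherever the erythroid list is described below. Mitosis genes were lower, with a median of -2.18 over 8 measured genes, below all random lists, and 6 of the 8 at least 2-fold lower. Top2a, a DNA topoisomerase of dividing cells, had 106.1 reads in the naive and 14 in the saline library (log2 fold -3.01, 95% interval -3.93 to -2.20), and Cdc20, an activator of the anaphase-promoting complex, had a log2 fold of -3.15 (95% interval -4.85 to -1.82).

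Genes of the acute phase and of IL-6 signalling were higher in the saline liver. The 17 positive acute phase genes had a median of 0.80, above all random lists, with 4 at least 2-fold higher, among them Lcn2 (2.25), Orm1 (1.95), Lbp (1.17) and Hp (1.07). Hamp, which encodes the iron hormone hepcidin, was the one member below 0, at -0.49. All 11 measured genes of IL-6 and STAT3 signalling were above 0, with a median of 0.74 (percentile 99.97), led by the oncostatin M receptor Osmr (3.14), the feedback inhibitor Socs3 (2.05), Bcl3 (1.56) and Stat3 (1.29). Il6 itself was listed at 0 in all 4 libraries. The 10 antigen presentation genes of MHC class II had a median of 1.02 (percentile 99.99), with RT1-DMb at 2.14, Ctss at 1.53 and RT1-Ba at 1.18. Cytokines and NF-kB targets had a median of 0.50 over 10 genes (percentile 99.11), with Il1b at 1.34 (95% interval 0.72 to 2.0) and Vcam1 at 1.27, while Nfkbia and Il1a were both at -1.21. This last call was lost with the mean of the list in place of the median.

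Markers of other cell types and of matrix were also higher. TGF beta, stellate cell and matrix genes had a median of 0.79 over 26 genes, above all random lists, with 10 at least 2-fold higher, such as Tagln (1.91), Col1a1 (1.75) and Tgfb3 (1.71, 95% interval 0.55 to 3.06). Lox, an enzyme that cross-links collagen, was at -2.86. Endothelial markers had a median of 0.58 over 17 genes (percentile 99.98), with Clec4g at 1.58, Cdh5 at 1.21 and Kdr at -0.47. Cholangiocyte and progenitor markers had a median of 0.85 over 8 genes (percentile 99.91), with Gpc3 at 3.61 (95% interval 1.61 to 6.73; 2 reads in the naive and 26 in the saline library) and Krt19 at 1.98 (95% interval 0.54 to 3.74). Mesenchymal stromal and adipose markers had a median of 0.52 over 8 genes (percentile 99.28), led by Fabp4 (2.97), with Car3 at -1.36; the call was lost with the mean of the list. Lists of neutrophils, T and NK cells, and B and plasma cells had fewer than 5 measured genes and are not described. Plasma proteins made by hepatocytes lay inside the random range, with a median of -0.05 over 17 genes and Alb, which encodes albumin, at -0.05.

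Lipid synthesis was lower in the saline liver. Lipogenesis had a median of -0.61 over 16 genes, below all random lists, with 5 at least 2-fold lower. They included the transcription factor Srebf1 (-2.12), Pnpla3 (-1.82) and Gpam (-1.48), while Acaca was at 0.63. With a mean of at least 50 normalized reads the lipogenesis median was -0.24 and the call was lost. Cholesterol synthesis and SREBP2 targets had a median of -0.29 over 24 genes (percentile 0.19), with Hmgcs1 at -1.55. Urea cycle and gluconeogenesis genes had a median of 0.31 over 15 genes (percentile 99.79), led by serine dehydratase Sds (2.70), with G6pc at -1.02 and Hal at -1.17. Growth factors and receptors had a median of -0.44 over 13 genes (percentile 0.14), with Fgf21 at -2.53 (95% interval -3.49 to -1.72), Igfals at -0.76 and Egfr at -0.59, and with Igfbp1 at 1.88. Immediate early genes had a median of -0.43 over 14 genes (percentile 0.28), with Dusp1 at -3.79, Egr1 at -1.71 and Zfp36 at -1.33, and with Ier3 at 1.05.

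Clock genes went both ways: of 15 measured, 4 were at least 2-fold higher and 5 at least 2-fold lower. The output genes Dbp (5.13) and Per3 (4.0) were far higher, and Bhlhe40 (-2.25), Cry1 (-1.47, 95% interval -2.13 to -0.84), Clock (-1.37) and Npas2 (-1.27, 95% interval -1.65 to -0.90) were lower. Their median was -0.29 (percentile 1.43) and their mean 0.30, so the list has no single direction. DNA replication and S phase genes had a median of -0.27 over 13 genes (percentile 2.48) with none past 2-fold, and cytosolic ribosomal proteins a median of 0.11 over 52 genes (percentile 98.18). Both calls were lost under at least 4 of 8 other settings. Among genes named for their size alone were Alox15 (gene ID 81639), which encodes a lipoxygenase, at 4.72 (95% interval 3.32 to 6.62), the metallothionein Mt2A at 3.95 and the cytokine signalling inhibitor Cish at 3.59 (95% interval 2.41 to 5.08), and at the low end Stac3 (-2.67), the glycogen-targeting phosphatase subunit Ppp1r3b (-2.64) and Mid1ip1 (-2.39). Of the genes fixed for every comparison, Hmox1, which encodes haem oxygenase 1, was at 2.17, Ppargc1a, which encodes the coactivator PGC-1 alpha, at 1.83, Tgfb1 at 0.90, Hgf at 0.24, Afp at -0.52, Ccnd1, which encodes cyclin D1, at -0.73 and the proliferation marker Mki67 at -1.54.

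In all, 19 of 33 lists were called in this comparison, where 1.65 would be by chance. Among the 1605 genes with recovered reads, 310 were at least 2-fold apart, and counting error alone gave a mean of 46.1 such genes over 100 simulated draws (range 29 to 67). The total of 975 genes depended on the pseudocount, and was 608 with a pseudocount of 5 and 203 with a pseudocount of 20. Genes without recovered reads were placed at the bottom of their level class for this, which shrinks their folds most. The drop therefore does not show that the differences lie in low genes, here or in the comparisons below.

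Of the 9824 genes, 359 were at least 2-fold higher and 98 at least 2-fold lower than naive in all 3 hepatectomised livers. The naive library enters all 3 folds, so the same count was made with each other library as the odd one out: 44 genes for the saline, 80 for the siRNC and 124 for the miR-27b library, against 457 for the naive library. Within the stricter set of 2999 genes with higher levels, those furthest above naive included Alox15, at 4.72, 4.31 and 5.60 in the saline, siRNC and miR-27b livers, and Mt2A, at 3.95, 2.99 and 3.82. The kininogen genes Kng1 and Kng1l1, close copies whose reads may be shared, were at 2.65 and 2.36 in the saline, 3.0 and 2.78 in the siRNC, and 4.23 and 4.18 in the miR-27b liver. Furthest below within that set were, among others, Stac3 (-2.67, -1.17 and -4.24), the nuclear receptor Ppard (-2.0, -1.99 and -1.70), the lipase inhibitor G0s2 (-1.83, -2.04 and -1.53), and Smad7, an inhibitor of TGF beta signalling (-1.67, -1.57 and -1.86).

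**Figure D1:**
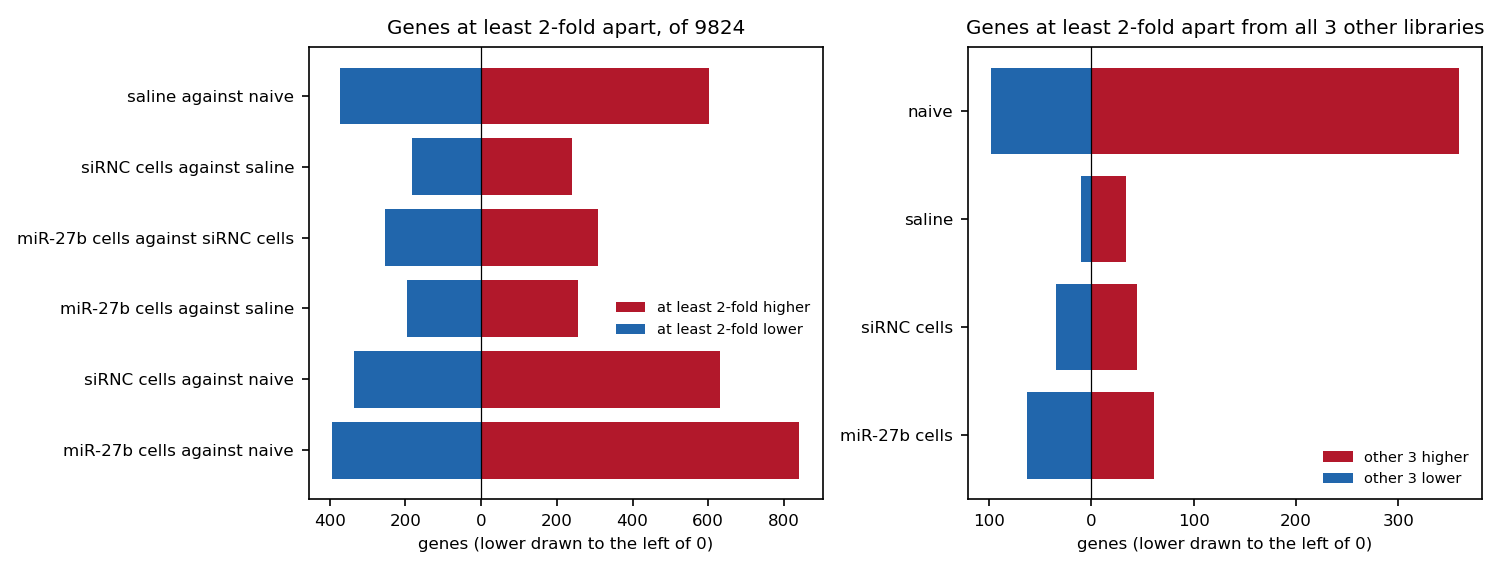
Left, number of genes at least 2-fold higher (right of 0) or lower (left of 0) in each pair of libraries, of 9824 genes. Right, number of genes in which 1 library lay at least 2-fold from all 3 others, with the naive library at 359 genes with the others higher and 98 with the others lower.

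The second comparison sets the siRNC liver, from the rat given the cells labelled siRNC, against the saline liver. The labels do not spell out siRNC, which is read here as a control. The saline library is also in the first comparison with opposite sign, so a gene displaced in that library alone appears in both. Of 9824 genes, 241 were at least 2-fold higher and 182 at least 2-fold lower. Genes of lipid synthesis were higher in the siRNC liver. Cholesterol synthesis and SREBP2 targets had a median of 1.08 over 24 genes, above all random lists, with 12 at least 2-fold higher and 23 above 0. They included Msmo1 (1.84) and Hmgcs1 (1.70), with Tm7sf2 at -0.46. Lipogenesis had a median of 0.77 over 16 genes, above all random lists, with 7 at least 2-fold higher, among them Pnpla3 (3.58), Srebf1 (2.16), fatty acid synthase Fasn (2.13) and Thrsp (1.63). Urea cycle and gluconeogenesis genes were lower, with a median of -0.30 over 15 genes (percentile 0.03), with the gluconeogenic enzymes G6pc at -1.65 and Pck1 at -1.12, Got1 at -1.21, and Hal at 0.59. Lpin1, which encodes a phosphatidate phosphatase, was at -2.40.

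Clock genes again moved in opposite ways, with a list median of 0.72 over 15 genes, above all random lists, 7 at least 2-fold higher and 3 at least 2-fold lower. Per2 (2.37), Dbp (1.59) and Per3 (1.54) were higher, and Arntl (-2.13) and Npas2 (-1.58, 95% interval -2.24 to -0.94) lower. Matrix genes had a median of 0.47 over 26 genes, above all random lists, with 6 at least 2-fold higher. Lum, which encodes the matrix proteoglycan lumican, had 3 reads in the saline and 82 in the siRNC library (log2 fold 4.82, 95% interval 3.22 to 7.13), Col1a1 was at 2.75 and Col1a2 at 1.42. With a mean of at least 50 normalized reads, 9 of these genes were left, their median was 0.10 and the call was lost. Erythroid genes had a median of -0.43 over 12 genes (percentile 0.01), with Hbq1 at -1.57, and cholangiocyte and progenitor markers a median of -0.46 over 8 genes (percentile 0.21), with Krt19 at -1.76 (95% interval -3.36 to -0.40). Genes reported as miR-27b targets had a median of 0.26 over 12 genes (percentile 99.07), with 8 above 0, and this list shares members with the lipid lists.

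Smaller shifts were seen in 4 lists, each lost under at least 1 other setting. ER stress and amino acid response genes had a median of 0.23 over 17 genes (percentile 99.42), with Herpud1 at 0.73 and Trib3 at -1.15. Acute phase genes had a median of -0.19 over 17 genes (percentile 1.28), with Lcn2 at -1.01 and A2m at 1.27. Pericentral hepatocyte genes had a median of -0.22 over 13 genes (percentile 1.53), with Tbx3 at -1.53 and with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 2.28. Cytochromes P450 of drug metabolism had a median of -0.14 over 23 genes (percentile 2.44), with Cyp2c24 at -2.82 and Cyp2b2 at -2.24; reads of these paralogs may be shared. By size alone, Cd274, which encodes the immune checkpoint ligand PD-L1, was at 3.37 (95% interval 2.69 to 4.13; 19 reads in the saline and 190.3 in the siRNC library), Mid1ip1 at 2.54 and Sult2a1 at 2.16, and the vasodilator peptide gene Adm was at -3.94. Of the fixed genes, Ccnd1 was at -1.27, Ppargc1a at -0.73, Mki67 at -0.71, Hgf at 0.21, Tgfb1 at -0.12, Afp at -0.05, Alb at -0.03 and Hmox1 at 0.02.

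In this comparison 12 of 33 lists were called, and mitosis genes were inside the random range (median 0.14 over 8 genes). Without the filter on low levels, the mitosis list had 24 genes and a median of -0.43 and was called lower. Among genes with recovered reads, 141 of 1605 were at least 2-fold apart, against a mean of 44.4 from counting error alone. The total of 423 genes was 232 with a pseudocount of 5 and 70 with a pseudocount of 20.

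**Figure D2:**
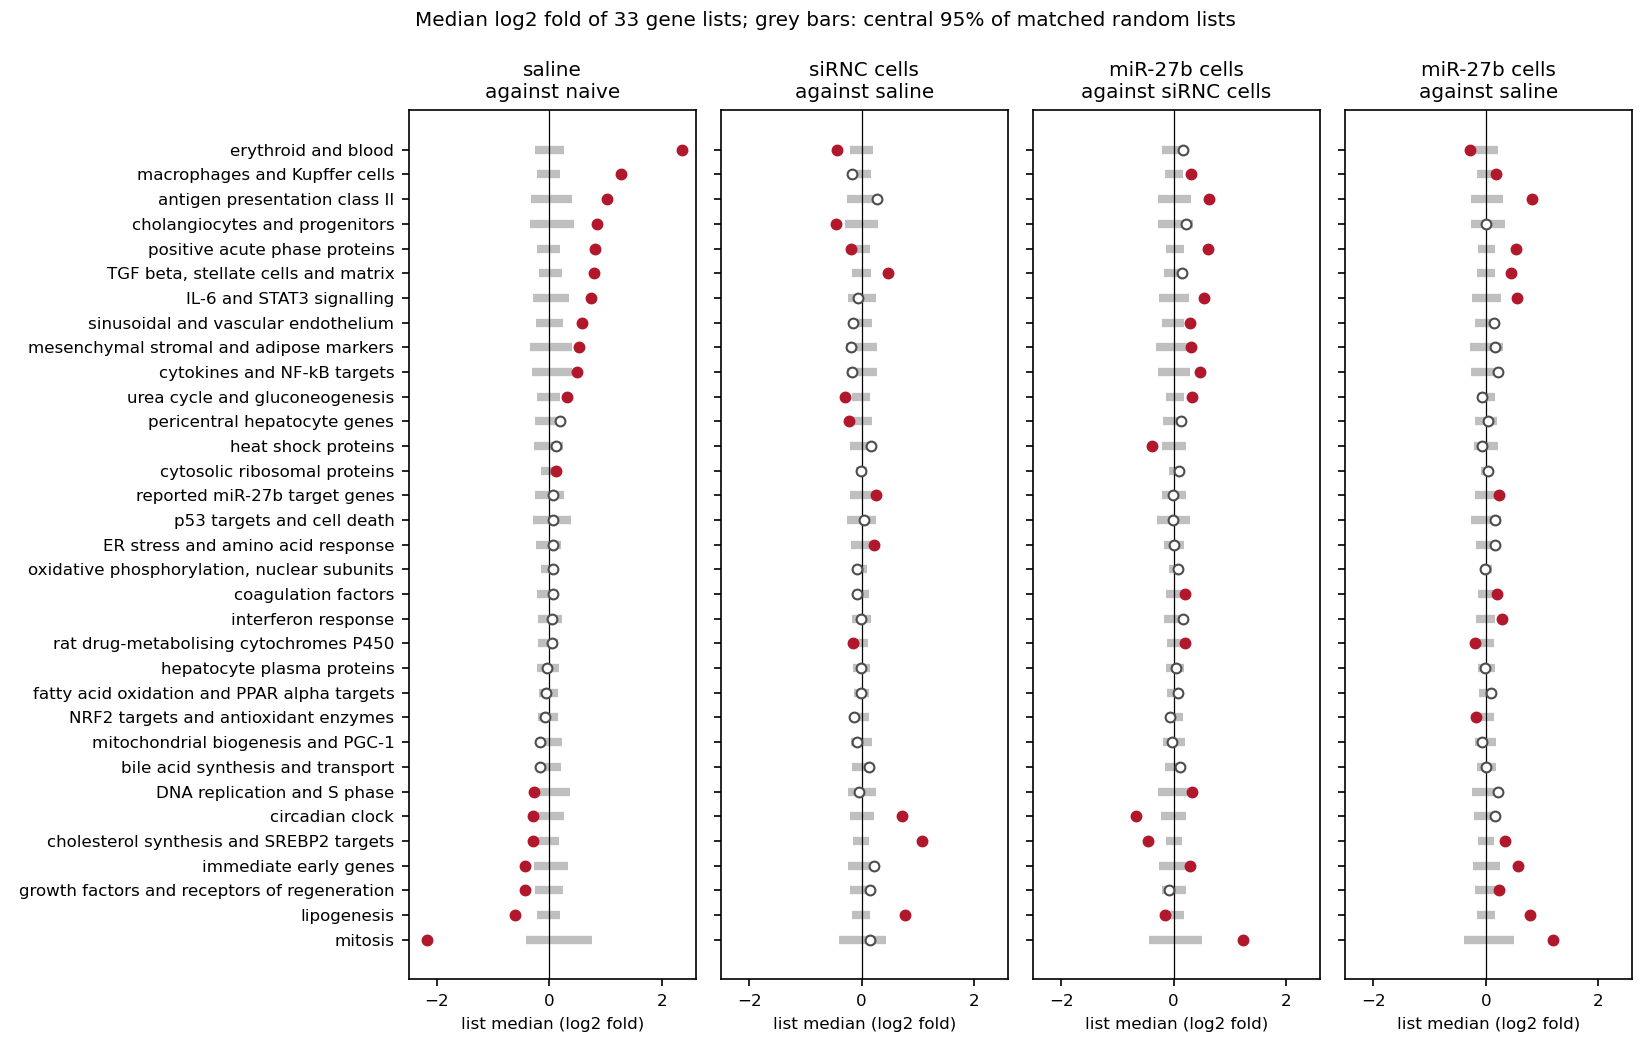
Median log2 fold of the 33 gene lists with at least 5 measured genes (points) in the 4 main comparisons, with the central 95% of matched random lists as grey bars; filled red points lie outside that range. Mitosis lies at -2.18 in saline against naive and at 1.24 in miR-27b against siRNC, and cholesterol synthesis at 1.08 in siRNC against saline and -0.46 in miR-27b against siRNC.

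The third comparison sets the liver given miR-27b cells against the liver given siRNC cells. The siRNC library is in this comparison and the previous one with opposite sign, so a gene displaced in that library alone appears in both, and a reversal between them is partly built in. Of 9824 genes, 310 were at least 2-fold higher and 253 at least 2-fold lower in the miR-27b liver. Mitosis genes were higher, with a median of 1.24 over 8 genes, above all random lists, and 5 at least 2-fold higher. Cenpf had 3 reads in the siRNC and 22 in the miR-27b library (log2 fold 2.95, 95% interval 1.21 to 5.33), cyclin gene Ccna2 had a log2 fold of 2.81 (95% interval 0.98 to 6.24), Mki67 was at 1.44 and Top2a at 1.31 (95% interval 0.44 to 2.26). DNA replication and S phase genes had a median of 0.32 over 13 genes (percentile 99.35), none past 2-fold, with Tk1 at 0.91 and Prim1 at 0.90 (95% interval 0.35 to 1.47). With a mean of at least 50 normalized reads, 6 of these genes were left and their median was -0.062.

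Acute phase genes were higher in the miR-27b liver, with a median of 0.61 over 17 genes, above all random lists, and 16 above 0. Lcn2 was at 4.2, Orm1 at 1.16, Lbp at 1.14 and Serpina3n at 1.03, while Hamp was at -4.16. IL-6 and STAT3 signalling had a median of 0.54 over 11 genes (percentile 99.97), with Bcl3 at 2.33, Socs3 at 1.85, Pim1 at 1.25 (95% interval 0.57 to 1.98) and Stat3 at 1.03. Cytokines and NF-kB targets had a median of 0.46 over 10 genes (percentile 99.77), led by the interleukin 1 receptor antagonist Il1rn (2.48). The 10 class II genes were all above 0, with a median of 0.63 (percentile 99.97) and RT1-Bb at 1.25. Macrophage markers had a median of 0.31 over 18 genes (percentile 99.97) with none past 2-fold, and endothelial markers a median of 0.30 over 17 genes (percentile 99.79), with Vwf at 1.23. Coagulation factors had a median of 0.19 over 18 genes (percentile 98.81), led by the fibrinogen chains Fga (0.88), Fgb (0.71) and Fgg (0.68), which are also in the acute phase list. Immediate early genes had a median of 0.29 over 14 genes (percentile 98.62), with Egr1 at 2.88 and Gadd45b at 2.01, and with Jun at -0.91. The calls for coagulation factors and for immediate early genes were each lost under 1 other setting. Mesenchymal stromal and adipose markers had a median of 0.31 over 8 genes (percentile 97.74), with Cd44 at 1.41 (95% interval 1.02 to 1.82), a call kept under only 3 of 7 other settings.

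Genes of cholesterol synthesis were lower in the miR-27b than in the siRNC liver. Cholesterol synthesis had a median of -0.46 over 24 genes, below all random lists, with Msmo1 at -1.61 and Hmgcs1 at -1.50, and with Insig1 at 0.68. Lipogenesis had a median of -0.16 over 16 genes (percentile 2.21) with none past 2-fold, and 0.007 with a mean of at least 50 normalized reads, a call kept under only 2 of 8 other settings. Urea cycle and gluconeogenesis genes had a median of 0.32 over 15 genes (percentile 99.97), with G6pc at 2.21 and Pck1 at 1.30. Clock genes had a median of -0.68 over 15 genes, below all random lists, with Per2 at -3.83, Per3 at -3.43 and Dbp at -3.18, and with Arntl at 2.29 and Npas2 at 2.05 (95% interval 1.44 to 2.70). Heat shock proteins had a median of -0.38 over 11 genes (percentile 0.07), with Dnajb1 at -0.97 and Hsph1 at -0.65; with a mean of at least 50 normalized reads the median was -0.11 and the call was lost. Cytochromes P450 had a median of 0.20 over 23 genes (percentile 99.68), with Cyp2c7 at 1.04 and Cyp2c11 at -0.91. The list of reported miR-27b targets lay inside the random range, with a median of -0.01 over 12 genes, 6 above 0 and 6 below. Matrix genes also lay inside it, with a median of 0.14 over 26 genes (percentile 94.21), 16 above 0 and 10 below. Lum (-4.29) and Col1a1 (-2.5), high in siRNC against saline, were lower here.

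By size alone, Adm was at 4.65, Lpin1 at 2.40, the sorting nexin gene Snx20 at 1.96 (95% interval 1.49 to 2.43) and Lrrc25 at 1.84 (95% interval 1.32 to 2.37), and at the low end Stac3 was at -3.07, the steroid dehydrogenase gene Hsd17b2 at -2.75, Cish at -2.74 (95% interval -3.49 to -2.05), Cd274 at -2.67 (95% interval -3.26 to -2.07) and Nrep at -2.01. Ppargc1a was at 1.85, Hmox1 at 0.85, Tgfb1 at 0.47, Afp at 0.34, Hgf at 0.21, Alb at 0.16 and Ccnd1 at -0.49. In this comparison 17 of 33 lists were called. Among genes with recovered reads 199 of 1605 were at least 2-fold apart, against a mean of 49.1 from counting error alone. The total of 563 genes was 309 with a pseudocount of 5 and 108 with a pseudocount of 20.

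The fourth comparison sets the miR-27b liver against the saline liver, without the siRNC library. Its miR-27b library is also in the third comparison, and its saline library in the first and second. A gene displaced in either library alone therefore appears again here, and a repeated call is no independent check. Of 9824 genes, 257 were at least 2-fold higher and 196 at least 2-fold lower. All 8 measured mitosis genes were above 0, with a median of 1.20, above all random lists, and 4 at least 2-fold higher: Cenpf (2.99, 95% interval 1.26 to 5.38), Ccna2 (2.12, 95% interval 0.49 to 4.16), Cdc20 (1.89, 95% interval 0.39 to 3.68) and Top2a (1.55, 95% interval 0.64 to 2.56). Against the naive liver the miR-27b liver had Cenpf at -0.09, Ccna2 at -0.70, Cdc20 at -1.26 and Top2a at -1.46. Lipogenesis had a median of 0.79 over 16 genes, above all random lists, with Pnpla3 at 3.12, Fasn at 1.92, Srebf1 at 1.45 and Thrsp at 1.33, and cholesterol synthesis a median of 0.34 over 24 genes, above all random lists, with the SREBP retention factor Insig1 at 1.98. Clock genes lay inside the random range, with a median of 0.16 and a mean of -0.18, but went both ways: 3 of 15 were at least 2-fold lower, Per3 (-1.89), Dbp (-1.59) and Per2 (-1.46), which are named after their values were seen.

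Acute phase, IL-6 signalling, class II and matrix genes were higher in the miR-27b than in the saline liver, while cytokines and NF-kB targets lay inside the random range (median 0.23 over 10 genes, percentile 94.25). Acute phase genes had a median of 0.53 over 17 genes, above all random lists, with Lcn2 at 3.19, A2m at 1.84 and Orm1 at 1.29, while Hamp was at -4.91, the lowest value among the named genes of this comparison. IL-6 and STAT3 signalling had a median of 0.55 over 11 genes (percentile 99.97), with Pim1 at 1.20 (95% interval 0.52 to 1.90), and 0.32 and no call with a mean of at least 50 normalized reads. Class II genes had a median of 0.81 over 10 genes, above all random lists, with the class II transactivator Ciita at 1.40 (95% interval 0.46 to 2.41), RT1-Db1 at 1.24 and Cd74 at 1.23. Immediate early genes had a median of 0.58 over 14 genes, above all random lists, led by Egr1 (3.18) and Zfp36 (1.33). Matrix genes had a median of 0.46 over 26 genes, above all random lists, with 23 above 0 and smooth muscle actin Acta2 at 2.14 (95% interval 1.45 to 2.88). Interferon response genes had a median of 0.29 over 22 genes (percentile 99.86), with Irf1 at 1.13 and Ifit3 at 0.90 (95% interval 0.39 to 1.42). Coagulation factors had a median of 0.20 over 18 genes (percentile 99.55), with Fga at 0.66.

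Cytochromes P450 had a median of -0.20 over 23 genes (percentile 0.17), with Cyp2c24 at -1.30, Cyp2b2 at -1.16 and Cyp2e1 at -0.67. NRF2 targets had a median of -0.17 over 21 genes (percentile 0.85), with Txnrd1 at -0.90 and Gclm at -0.84, and with Hmox1 at 0.87, a call lost against unmatched random lists. Erythroid genes had a median of -0.28 over 12 genes (percentile 0.35), with Hba2 at -0.42. Macrophage markers (median 0.18 over 18 genes, percentile 98.30), growth factors and receptors (0.24 over 13 genes, percentile 98.38) and reported miR-27b targets (0.23 over 12 genes, percentile 98.23) were called higher, and these calls were kept under 4, 6 and 3 of 8 other settings. Fgf21 was at 1.30 (95% interval 0.37 to 2.33) and Igfbp1 at 1.05, and among the miR-27b targets Lpl was at 0.84 and Dll4 at -0.62 (95% interval -1.65 to 0.36).

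By size alone, S100a13 was at 1.83 (95% interval 1.22 to 2.49), Kng1l1 at 1.83, Cyp7a1 at 1.61 and the myeloid tyrosine kinase Fgr at 1.61 (95% interval 1.09 to 2.18), and at the low end Fam65b was at -1.88 (95% interval -2.61 to -1.21), Cep112 at -1.86 (95% interval -2.41 to -1.34), Tmem25 at -1.83 (95% interval -2.48 to -1.22), Cish at -1.82 (95% interval -2.61 to -1.10) and Ccnd1 at -1.76. Ppargc1a was at 1.12, Mki67 at 0.73, Hgf at 0.42, Tgfb1 at 0.35, Afp at 0.29 and Alb at 0.13. In this comparison 16 of 33 lists were called, and 188 of 1605 genes with recovered reads were at least 2-fold apart, against a mean of 46.8 from counting error alone. The total of 453 genes was 233 with a pseudocount of 5 and 76 with a pseudocount of 20.

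**Figure D3:**
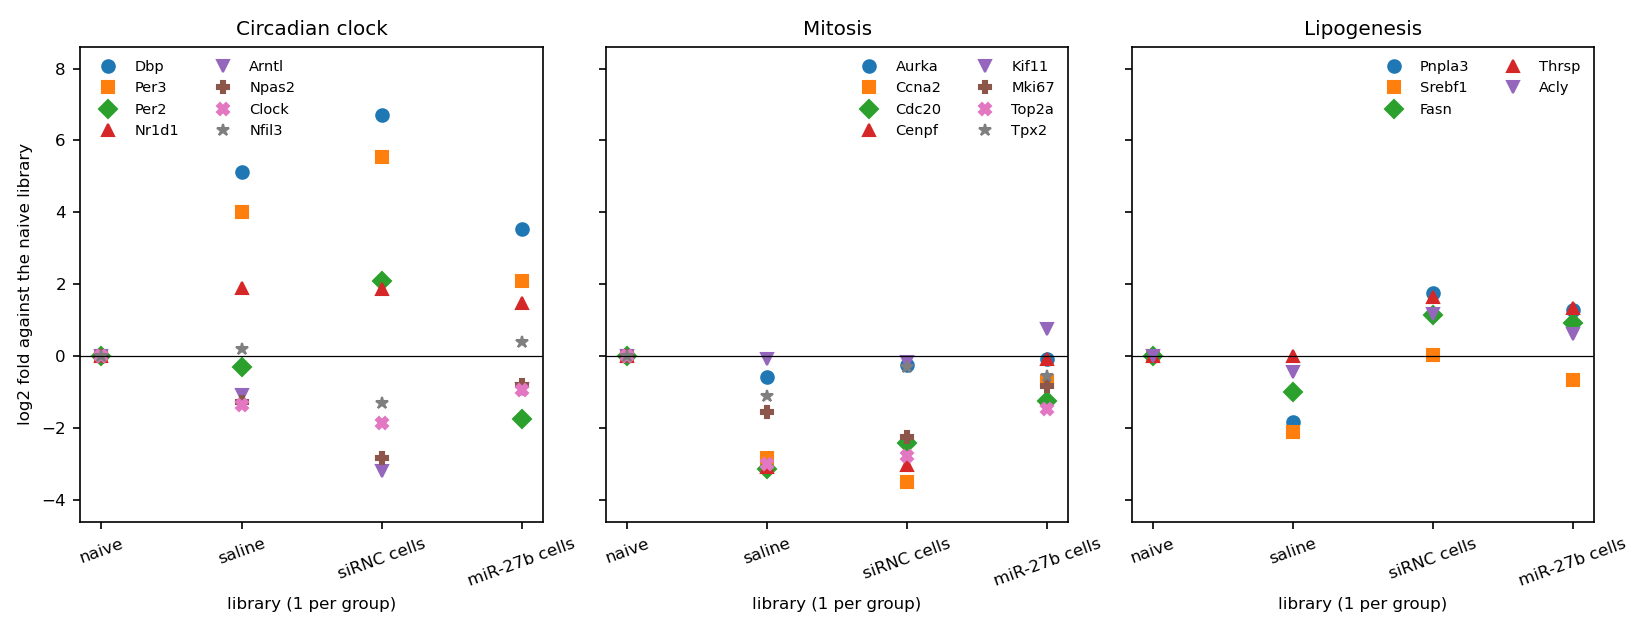
Log2 fold against the naive library (0 by construction) for 8 clock genes, the 8 measured mitosis genes and 5 lipogenesis genes; each point is 1 library. Dbp lies at 5.13 in the saline, 6.72 in the siRNC and 3.54 in the miR-27b liver, and Arntl at -1.07, -3.20 and -0.91.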

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

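The count over genes with recovered reads alone was chosen after seeing the data, as was the move of the pseudocount of 5 from the planned main scale to an alternative; the other settings were planned. Counts are given in the order saline against naive, siRNC against saline, miR-27b against siRNC, miR-27b against saline, and all 3 hepatectomised livers against naive. The numbers of genes at least 2-fold apart were 975, 423, 563, 453 and 457. A pseudocount of 1 and centring on the median kept each within 1.5 times. They were 608, 232, 309, 233 and 231 with a pseudocount of 5, and 203, 70, 108, 76 and 80 with a pseudocount of 20, which shrinks folds of low genes by construction. It also shrinks folds of genes without recovered reads, as these were placed at the bottom of their level class whatever their true level. How much of the drop comes from that placement was not tested. With no filter on low levels they were 1942, 1132, 1492, 1311 and 828, and with a mean of at least 50 they were 186, 76, 99, 71 and 87, where fewer genes enter. Among genes with recovered reads alone they were 310, 141, 199, 188 and 162. An adjusted p under 0.05 in an exact binomial test of those reads, which compares the libraries and not the conditions, left 216, 73, 110 and 100 in the first 4. The share of genes higher among all at least 2-fold apart was 61.6% in saline against naive and 52.2% with a pseudocount of 20, and for all 3 against naive 78.6% and 57.5%, and 68.5% with no filter; in siRNC against saline it was 57.0%, and 70.0% with a pseudocount of 20. Of 64 list calls, 42 were kept under every setting run, though mitosis and other lists left with under 5 genes could not be run with a mean of at least 50, and 22 were lost under at least 1. Centring on the median shifts a list and its random lists alike, so it could not test a call. It is still counted among the 8 settings. With a mean of at least 50, 10 lists were called in saline against naive, 8 in miR-27b against siRNC and 10 in miR-27b against saline, in place of 19, 17 and 16; fewer lists and genes enter. Among called lists, signs turned for S phase (-0.062) and lipogenesis (0.007) in miR-27b against siRNC with a mean of at least 50, and for clock genes in saline against naive with the mean in place of the median (0.30). Lists not called in the main analysis came to be called on the other side of the random lists for reported miR-27b targets in saline against naive with a mean of at least 50 (-0.39), for mitosis in siRNC against saline with no filter (-0.43), and with the mean in place of the median for NRF2 targets in saline against naive (0.26) and fatty acid oxidation in siRNC against saline (-0.16, where the median of -0.01 was already below 0). Signs of some further lists, called under neither setting, also turned. Of 444 folds of named genes, 36 moved with a pseudocount of 1, 132 with 5 and 220 with 20, beyond their counting interval or, without recovered reads, by 0.13 or more. The cause was not tested, beyond the different genes or summary that enter. Rescaling to CPM, by TMM or by the upper quartile was not run, since it needs gene levels that within-gene differences do not give. No paired analysis was possible because each group has 1 library. Depth limits the low genes: at 16 reads in each library a 2-fold difference is about 2 counting SDs.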

Other observations

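The tests on counting error, on the hepatocyte share and on lipogenesis against the clock were chosen only after the result was seen. Some single genes outside the fixed lists were also chosen after their values were seen. Bcl6, a transcriptional repressor, was at -4.67 in saline against naive and 2.65 in miR-27b against saline. Gadd45g, a stress-inducible gene, was at -2.15 in miR-27b against saline. Wee1, a kinase that restrains entry into mitosis and a member of the clock output genes tested below, was at -2.53 in miR-27b against siRNC.

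Among the 15 measured clock genes, 10 were put in 2 groups after their values were seen: Dbp, Per2, Per3, Nr1d1, Nr1d2 and Tef had medians of 1.51, 1.10, -2.05 and -0.93 in saline against naive, siRNC against saline, miR-27b against siRNC and miR-27b against saline, and Arntl, Npas2, Clock and Nfil3 had medians of -1.17, -1.55, 1.87 and 0.31. In saline against naive, Per2 (-0.29) and Nfil3 (0.21) lay on the other side of 0 from their group medians. The other 5 (Bhlhe40, Cry1, Cry2, Per1 and Hlf, listed as LOC690286) were below 0 in saline against naive, unlike the median of the Dbp group, and on the side of that median in the next 2 comparisons. Counting error argues poorly for these clock differences, as 6 of all 15 genes lay beyond 2 counting SDs at 16 reads in miR-27b against siRNC. A candidate explanation is a different clock phase at sampling, for which output genes outside the fixed clock list should follow Dbp: the median of 6 such genes had its sign in 3 of 3 steps, the first 3 of these comparisons (0.64, 0.05 and -0.35), but lay outside the central 95% of random lists in 1 step alone (percentiles 99.02, 60.28 and 4.10), where at least 2 had been required. The list first run also held Hlf and Ciart, which are in the fixed clock list and were taken out after its result was seen; of these Hlf alone was measured, and with it 2 steps lay outside (medians 0.60, 0.09 and -0.50, percentiles 99.30, 72.95 and 0.49), so the outcome rests on that 1 gene. Clock phase, which with 1 animal per group goes with treatment, cannot be told apart from it, and an effect of surgery or cells stays open, untested.

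Lipid synthesis was higher and gluconeogenesis lower in the siRNC than in the saline liver, and cholesterol synthesis and gluconeogenesis turned in miR-27b against siRNC. In miR-27b against saline, urea cycle and gluconeogenesis genes lay inside the random range (median -0.07 over 15 genes, percentile 13.06). Counting error argues poorly here, as 19 of 40 measured cholesterol and lipogenesis genes were at least 2-fold higher in siRNC against saline, where 1.0 is expected at 16 reads. Different nutritional states may contribute, but the prediction written for 9 fasting-induced genes did not hold: of 2 medians 0 were as predicted (-0.10 and 0.07, inside the random range), which met the bound set beforehand against this explanation. That bound was judged wrong after the result was seen, since the members went both ways (Gadd45g at -1.82 and Bcl6 at 1.97 in siRNC against saline) and a median near 0 over such members decides nothing, so nutrition and treatment cannot be told apart. Nor can clock phase: lipogenesis was at -0.16 where the 2 clock groups differed most (-3.92), at -0.61 and 0.77 where they differed by 2.68 and 2.65, and at 0.79 where they differed least (-1.24, miR-27b against saline), which argues against a relation in 1 direction, but a phase need not act in 1 direction and no step had a difference small enough for the bound set.

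Markers of macrophages, endothelium and red cells were higher in all 3 hepatectomised livers. A lower share of hepatocytes alone would raise the markers of other cells alike, and this was not seen: the macrophage median exceeded the endothelial one by 0.69 in the saline liver (bootstrap 95% interval over genes 0.36 to 1.29), by 0.82 in the siRNC liver (0.54 to 1.24) and by 0.82 in the miR-27b liver (0.18 to 1.35). These intervals cover the spread over genes within a library, not between animals. The values argue against a lower share as the only cause. They cannot exclude it as a part, since endothelial markers were higher too. More blood left in the tissue could raise haemoglobin genes, and platelet genes were set as its test, but only 4 passed the level filter, with medians of 0.61, 0.57 and 0.50 against naive, too few to decide. A lower hepatocyte share in part, a change in macrophages themselves and an effect of surgery stay open, untested.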
